A study of Homo sapiens with 12 samples.

How the data were processed

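The series profiled cytoplasmic RNA from the human breast carcinoma cell line Cal51 on 12 Illumina bead arrays. Per the labels' protocols, cells received a control siRNA or an siRNA against IPMK, the inositol polyphosphate multikinase, and were harvested 72 hours after transfection. Arrays described as treated came from cells that had spent the last 24 hours in mitomycin C (MMC), a drug that crosslinks the DNA strands. The cytoplasmic fraction was taken by permeabilising the plasma membrane with digitonin, per the labels' protocols. Each of the 4 combinations of siRNA and treatment holds 3 arrays, numbered as experiments 1 to 3.

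The bead summary table gives, per the file headers, a mean intensity per probe and array, a detection p-value, and the number of beads, for 48802 probes. Column totals and distributions differed between arrays, so no normalization between arrays was visible in these deposited intensities, and whether the image software subtracted a background is not recorded. The deposited detection p-values rank each probe among the negative controls of its own array. A second deposited table, the authors' processed values, is on a log2-like scale. Its columns all have a median of 8.82 and the same sorted values to within 0.001, which is what quantile normalization between arrays leaves. Each of its columns correlated most with the intensities of its own array, with r across probes from 0.968 to 0.990 after removing each probe's mean. Its 14853 probes were exactly those with a detection p under 0.01 on at least 1 array. The R package lumi was used, per the submitters' processing notes, with no version or settings given, and the transform behind the log2-like scale stays unknown.

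Probes were named from GEO's annotation of the array platform. It lists 12852 probes of the authors' table, of which 12850 have 1 gene symbol and 2 have several, and symbols were updated through Entrez identifiers where the RefSeq gene table held them, which was so for 12847 probes. The other 2001 probes are unnamed here, and no probe was named IPMK, so the depletion itself could not be read from these arrays. Genome positions were not used here.

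The intensities were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background with a normal-exponential model whose parameters were inferred from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept, which left 13830 probes. Of these, 12086 had 1 symbol, 2 had several and 1742 were unnamed. For each gene the probe with the highest mean log2 signal was used, giving 9409 genes, 2219 of which had more than 1 probe. Probes of the same gene gave opposite calls for 16 genes in the untreated depletion comparison, 21 in the depletion comparison with MMC and 53 in the mean depletion effect, and for 0 genes in the MMC comparisons and the difference between them.

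Between 12122 and 13458 probes were detected per array, and the median number of beads per probe was 20 or 21. Arrays carry no read depth, and the number of arrays limits the precision. One linear model with 4 group means was fitted to all 12 arrays, so that the groups share an estimate of the spread, with moderated variances that follow the mean signal. It compared siIPMK with control siRNA without MMC and with MMC, MMC with no treatment under each siRNA, the difference between the MMC changes under both siRNAs, and the mean of both depletion effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 by limma's moderated test, and every adjusted p of a gene is from that test unless another fit is named. Errors of log2 changes are standard errors of the fit with 3 arrays per group, and errors of group means are standard deviations.

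The groups, comparisons, thresholds, fixed genes and 35 gene lists were chosen before the data were examined. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01 and, as a stricter reading, with the correlation estimated from the arrays, and adjusted over the 34 lists with at least 5 measured genes. With the estimated correlation, 0 lists passed in either depletion comparison, with lowest adjusted p values of 0.169 and 0.272, against 20 and 22 lists at the preset correlation. Only the p53 target list passed with the estimated correlation in the MMC comparisons and in their difference. With the terms for pairs of arrays described below, it passed in none of these at the estimated correlation. The leukocyte marker list had 2 measured genes and was not tested.

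Named genes follow a rule. They are the 10 with the largest rise and the 10 with the largest fall, among genes that passed with no overlap between the replicates, in both depletion comparisons and the MMC comparison under control siRNA. In the other comparisons 5 and 5 were taken, or the lowest unadjusted p values where none passed. The rule adds the 4 members of each described list with the lowest adjusted p and 16 genes fixed by name besides IPMK, of which 12 were measured. Where every array of a group lacked detection of a probe, the fold is a lower bound. It compares the mean of the detected group with the mean, over the arrays of the dim group, of the higher of the probe's own value and the lowest normalized value among that array's detected probes, and it is written as "at least".

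Whether the experiment numbers pair the arrays was checked from the correlation, across genes, of deviations from group means. Between untreated and MMC arrays of the same number it was 0.486, 0.193 and 0.419 under control siRNA and 0.704, 0.545 and 0.346 under siIPMK. Of the 6 arrays of each siRNA, 6 under control siRNA and 4 under siIPMK correlated best with the array of their own number. Numbers were taken to pair the arrays within each siRNA, although the labels only number the experiments. A fit with a term for each of these 6 pairs is given beside the MMC results for the counts of genes and of the lists described, and for some of the genes whose call it changed. It was chosen after the data were seen.

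The sensitivity of the fit was tested on simulated data for the real genes. With 100 genes changed per fold size, 50% of 1.5-fold and 79% of 2-fold changes were recovered in the untreated depletion comparison and 6.52% of 138 calls were false. In the MMC comparison under control siRNA, 40% and 86% were recovered and 5.97% of 134 calls were false. The list test at the preset correlation called the 1 shifted list of 20 and 0 of the others. Noise was drawn independently for each gene, so the simulation cannot show how that test fares with correlated genes. The simulated arrays also held no pairs, and far fewer genes were changed than were called for depletion in the data.

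Alternatives covered the background correction, the offset, median scaling and cyclic loess, the authors' value table, the detection filter, the choice of probe, blocks for the experiment, the variance model, array weights, thresholds, and each array left out in turn. With median scaling the median log2 change of all 9409 genes was 0.13 for depletion without MMC, 0.14 with MMC and 0.13 for the mean effect, against 0, 0.01 and 0 with quantile normalization, so depletion changes near these sizes are relative to the scaling. Median scaling equalized the median of all 48802 probes of each array, while at most 13458 probes were detected on any array. It therefore rests on undetected probes.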

Results

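The arrays measured transcript abundance in the digitonin-soluble cytoplasm of Cal51 cells, in 4 groups of 3 arrays: control siRNA and siIPMK, each without and with MMC for 24 hours. The number of detected probes was 12303 ± 216 (SD, n = 3) with control siRNA alone, 12598 ± 115 with control siRNA and MMC, 13223 ± 207 with siIPMK alone and 13233 ± 137 with siIPMK and MMC. Correlations across genes between arrays of the same group ran from 0.976 to 0.994. The first principal component held 67.5% of the variance and parted the siRNAs. On it the siIPMK arrays of experiment 1, without and with MMC, lay at 6.64 and 11.97, between the control arrays, which spanned -30.4 to -22.7, and the siIPMK arrays of experiments 2 and 3, which spanned 32.2 to 38.4. No probe carried the name IPMK, so the level of the targeted transcript is not reported.

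**Figure D1:**
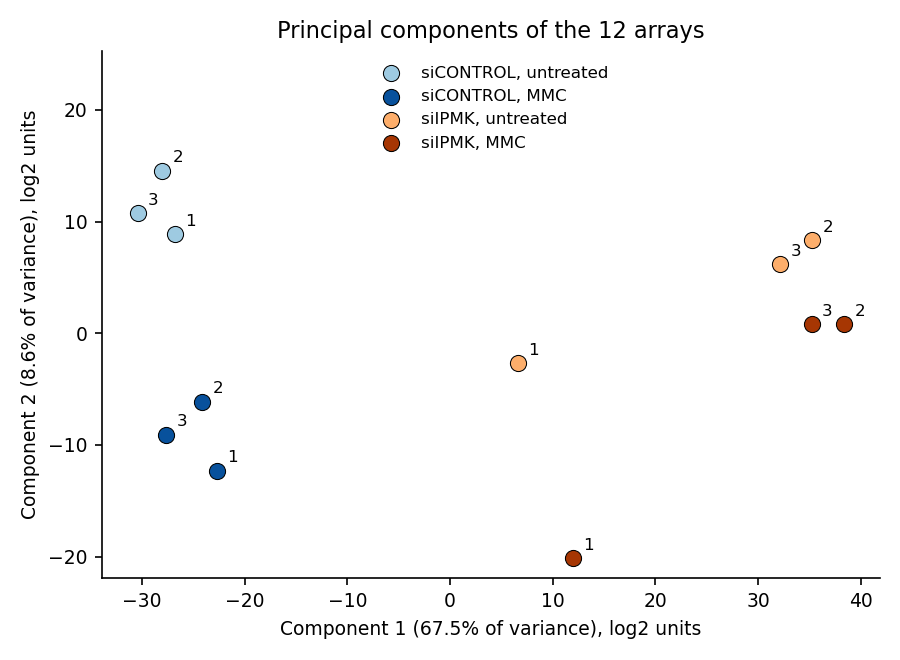
Positions of the 12 arrays on the first and second principal components of normalized log2 signal, coloured by group and numbered by experiment. Component 1, with 67.5% of the variance, parts control siRNA from siIPMK arrays, and the siIPMK arrays of experiment 1 lie between.

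The first question was which cytoplasmic transcripts differed after IPMK depletion in cells that had seen no MMC. At the preset correlation the lists of mitosis, DNA replication, homologous recombination, crosslink repair and checkpoint genes passed with medians under 0, and those of p53 targets and of secreted and membrane proteins with medians over 0. No list passed with an estimated correlation (lowest adjusted p = 0.169). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.92 ± 0.15 (log2, n = 3, adjusted p = 3.88e-06), from 12.13 ± 0.04 to 14.05 ± 0.44. GDF15, a secreted stress cytokine and p53 target, rose by 2.82 ± 0.27 (adjusted p = 8.48e-06). TK1, the thymidine kinase of S phase, fell by 2.53 ± 0.39 (adjusted p = 2.38e-04), and SPC24, a kinetochore subunit, fell by 2.25 ± 0.28 (adjusted p = 6.11e-05). In limma, 1922 genes rose and 1868 fell of 9409 tested, 430 and 277 of them by at least 2-fold. Replicates of the 2 groups did not overlap for 52.2% of the genes, where chance gives 10%. The share of calls that were rises was 50.7%, and 69.6% with median scaling.

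Among the other large rises, RPPH1, the RNA of ribonuclease P, was 8.64-fold higher (log2 3.11 ± 0.14). DGKB, a diacylglycerol kinase, was not detected on any control array and was at least 2.95-fold higher. The same held for DHRS2, a mitochondrial reductase, at least 2.90-fold higher, TDO2, which opens the tryptophan ring, at least 2.27-fold, the complement protease C1S, at least 2.02-fold, and the small heat shock protein HSPB8, at least 1.63-fold. TNFSF9, a costimulatory ligand, rose by 2.86 ± 0.38 and LBH, a transcriptional cofactor, by 2.63 ± 0.36, each detected on 2 of the 3 control arrays. CD44, the hyaluronan receptor, rose by 2.55 ± 0.26. Among the falls TMEM30A, a flippase subunit (adjusted p = 2.66e-05), TPD52 (adjusted p = 1.67e-04) and LRTOMT (adjusted p = 1.55e-05) were each detected on 1 of the 3 siIPMK arrays, so no size is given for them. MIS18A, which helps load the centromeric histone, fell by 2.50 ± 0.36, the endosomal GTPase RAB22A by 2.39 ± 0.22, HEYL, a Notch-responsive repressor, by 2.34 ± 0.32, the ornithine carrier SLC25A15 by 2.33 ± 0.31, and SEM1, a small subunit of the proteasome and of the BRCA2 complex, by 2.26 ± 0.31.

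The mitosis list, of spindle, kinetochore and anaphase genes, had a median change of -0.71. Of its 54 measured genes 0 rose, 42 fell and 12 did not pass, and 48 fell when adjusted over the list alone (camera adjusted p = 3.06e-11). That call was lost with an estimated correlation, adjusted p = 0.314. Besides SPC24, BIRC5, the survivin of the chromosomal passenger complex, fell by 2.01 ± 0.28, CDC20, the activator of the anaphase-promoting complex, by 1.06 ± 0.16, and the mitotic kinase PLK1 by 1.20 ± 0.22. CCNB1, cyclin B1, fell by 0.76 ± 0.27 (adjusted p = 0.0355), with overlap between the replicates. Of 46 DNA replication genes, 0 rose and 33 fell, also 33 when adjusted over the list alone, with a median of -0.61 (camera adjusted p = 2.05e-09; adjusted p = 0.282 with an estimated correlation). Among them POLE3, a histone-fold subunit of DNA polymerase epsilon, fell by 1.73 ± 0.20, the helicase factor CDC45 by 1.43 ± 0.18 and the licensing factor CDT1 by 1.31 ± 0.14.

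The lists of DNA repair were of most direct interest to a study of genome integrity. In both depletion comparisons the mitosis and replication lists had lower medians than the homologous recombination, Fanconi and checkpoint lists. Whether the falls of repair and checkpoint genes are separate from those of mitosis and replication genes was not tested. Homologous recombination genes had a median of -0.38. Of the 31 measured, 1 rose and 16 fell, as they did adjusted over the list alone (camera adjusted p = 7.21e-04; adjusted p = 0.282 with an estimated correlation). The nuclease EXO1 fell by 1.07 ± 0.15 and RPA1, which coats single-stranded DNA, by 0.78 ± 0.11. BRCA1 fell by 0.64 ± 0.17 (adjusted p = 0.00724), whereas PALB2, at -0.16 ± 0.14, and XRCC2, at -0.26 ± 0.20, did not pass. In the Fanconi anaemia and crosslink repair list, 1 of 24 measured genes rose and 11 fell, with the same counts adjusted over the list alone and a median of -0.33 (camera adjusted p = 0.0199; adjusted p = 0.314 with an estimated correlation). FANCI, a subunit of the complex that marks crosslinks, fell by 1.10 ± 0.21 (adjusted p = 0.00106), FANCG by 0.98 ± 0.15 and FANCE by 0.95 ± 0.14, and REV3L, the catalytic subunit of polymerase zeta, rose by 0.93 ± 0.19. Of 22 checkpoint genes 0 rose and 14 fell, or 1 and 14 adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.00145; adjusted p = 0.282 with an estimated correlation). CHEK1, the checkpoint kinase 1, fell by 0.63 ± 0.14 (adjusted p = 0.00258) and TELO2, a chaperone of the ATM and ATR kinases, by 1.25 ± 0.13, while ATM itself was at -0.05 ± 0.19 (adjusted p = 0.857). Mismatch and base excision repair had 0 rises and 12 falls among 23 genes (camera adjusted p = 2.20e-04; adjusted p = 0.282 with an estimated correlation), led by the glycosylase TDG at -1.13 ± 0.13. Nucleotide excision repair, with 4 rises and 5 falls among 24 genes, and end joining, with 1 and 3 among 7, did not pass (camera adjusted p = 0.709 and 0.0989).

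**Figure D2:**
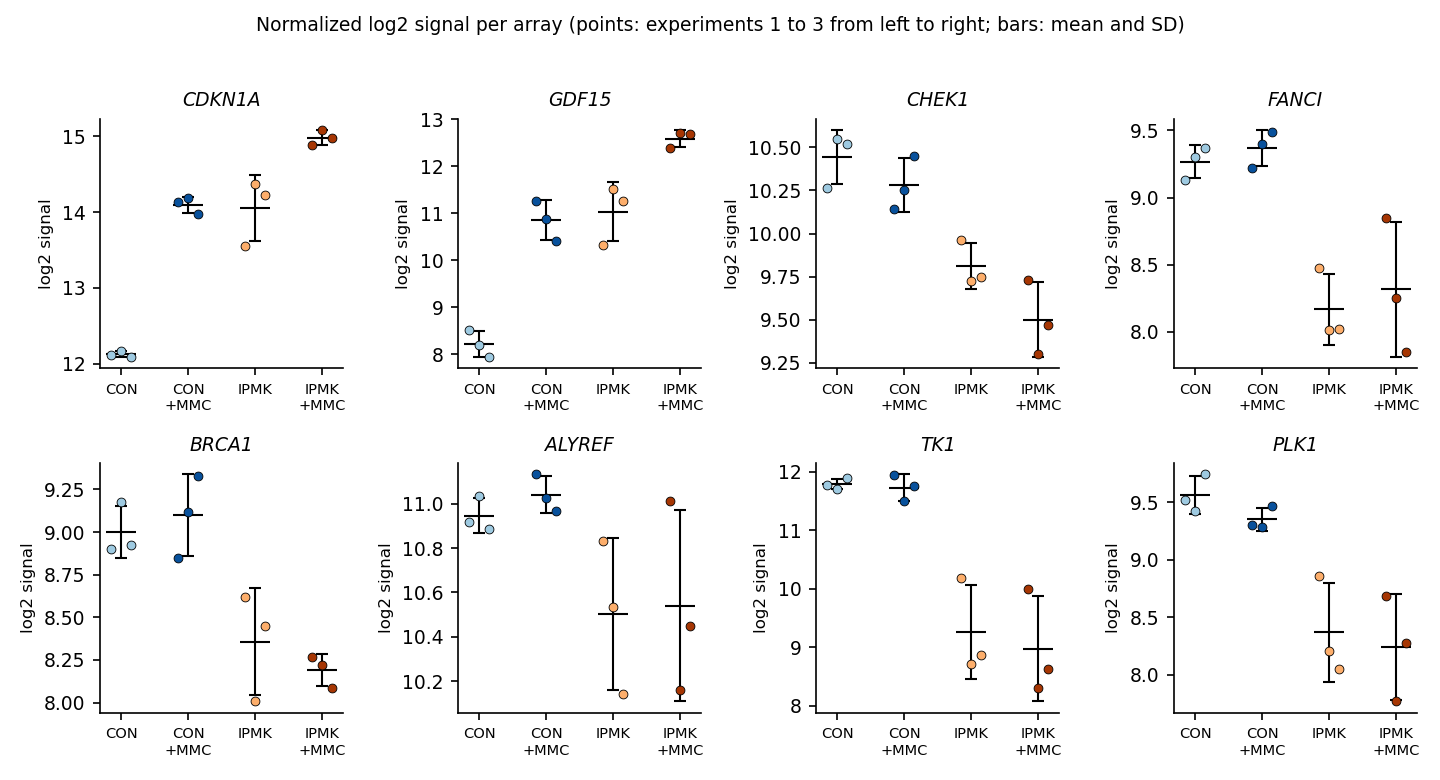
Normalized log2 signal of CDKN1A, GDF15, CHEK1, FANCI, BRCA1, ALYREF, TK1 and PLK1 on each array, with the mean and SD of each group of 3. The CDKN1A means are 12.13 with control siRNA, 14.10 with control siRNA and MMC, 14.05 with siIPMK and 14.98 with siIPMK and MMC.

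Factors of mRNA export were asked about because the series title names nuclear export. Of 43 measured export factors 2 rose and 14 fell, the same adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.00383; adjusted p = 0.314 with an estimated correlation). The helicase DDX19A fell by 0.98 ± 0.12 and MAGOH, of the exon junction complex, by 0.78 ± 0.12. ALYREF, the adaptor of the TREX complex, was at -0.44 ± 0.19 (adjusted p = 0.0784). Nuclear pore genes had 2 rises and 12 falls among 27, or 3 and 14 adjusted over the list alone (camera adjusted p = 0.00564; adjusted p = 0.282 with an estimated correlation), led by NUP37 at -0.89 ± 0.11. Of 8 measured RNAs of the list fixed as nuclear-retained, 4 rose and 2 fell, with a median of 0.49 that did not pass (camera adjusted p = 0.0944). How strictly each of them stays in the nucleus was not examined. SNORD13, a small nucleolar RNA, rose by 1.61 ± 0.20 and TUG1 fell by 0.44 ± 0.10.

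Of 41 measured p53 target genes 29 rose and 2 fell, the same adjusted over the list alone, with a median of 0.63 (camera adjusted p = 1.69e-07; adjusted p = 0.169 with an estimated correlation). DRAM1, a regulator of autophagy, rose by 1.86 ± 0.16 and GADD45A, a growth arrest gene, by 1.40 ± 0.14. MDM2, the ubiquitin ligase of p53, rose (adjusted p = 0.0167), but it was detected on 0 of 3 control and 2 of 3 siIPMK arrays and no bound can be given for the size of its rise. FOXO target genes had 13 rises and 0 falls among 23, or 14 and 0 adjusted over the list alone (median 0.51, camera adjusted p = 2.87e-05; adjusted p = 0.169 with an estimated correlation), with IRS2, an insulin receptor adaptor, up by 1.11 ± 0.15 and cyclin G2, CCNG2, up by 1.10 ± 0.13. Of 31 transcripts of secreted and membrane matrix proteins 19 rose and 2 fell, or 21 and 2 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.83e-05; adjusted p = 0.341 with an estimated correlation). Examples are TIMP2, an inhibitor of metalloproteinases, at 1.46 ± 0.20, APP at 1.39 ± 0.21 and the laminin chain LAMB1 at 1.14 ± 0.18. Endoplasmic reticulum chaperones and translocon genes, translated at the same membrane, had 11 rises and 2 falls among 28, or 12 and 3 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.0243; adjusted p = 0.634 with an estimated correlation), and with median scaling they did not pass (camera adjusted p = 0.0549).

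Cholesterol biosynthesis fell, with 0 rises and 11 falls among 19 genes, 14 when adjusted over the list alone, and a median of -0.59 (camera adjusted p = 4.25e-05; adjusted p = 0.169 with an estimated correlation). The isoprenoid enzymes IDI1 and FDPS fell by 2.01 ± 0.30 and 1.24 ± 0.13. Splicing factors had 0 rises and 24 falls among 54 (camera adjusted p = 4.25e-05; adjusted p = 0.314 with an estimated correlation), and ribosome biogenesis had 0 and 23 among 47, or 1 and 25 adjusted over the list alone (camera adjusted p = 3.59e-05; adjusted p = 0.282 with an estimated correlation). Oxidative phosphorylation had 5 rises and 19 falls among 63 (camera adjusted p = 0.0155; adjusted p = 0.282 with an estimated correlation), and G1/S cyclins and E2F factors had 2 and 9 among 20, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.0362; adjusted p = 0.282 with an estimated correlation). In that list cyclin E1, CCNE1, fell by 0.59 ± 0.12, while cyclin D1, CCND1, rose by 0.77 ± 0.14 and the retinoblastoma gene RB1 by 0.66 ± 0.11. Glycolysis and hypoxia genes had 14 rises and 3 falls among 32 (camera adjusted p = 0.00623; adjusted p = 0.321 with an estimated correlation), with the glucose transporter SLC2A1 up by 1.88 ± 0.30. Interferon response genes had 13 rises and 2 falls among 26 (camera adjusted p = 0.0117; adjusted p = 0.282 with an estimated correlation), and breast lineage markers had 8 rises and 0 falls among 14 (camera adjusted p = 0.00165; adjusted p = 0.255 with an estimated correlation), with the glycoprotein CD24 up by 1.16 ± 0.13.

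The lists of NF-kB and inflammatory genes (4 rises, 0 falls of 16), the ATF4 and unfolded protein response (12 and 8 of 32), serum response (9 and 4 of 37), apoptosis regulators (6 and 4 of 28), replication-dependent histones (8 and 3 of 18), ribosomal proteins (2 and 9 of 69), proteasome (7 and 3 of 34) and heat shock (5 and 4 of 20) did not pass as lists, with camera adjusted p from 0.074 to 0.709. The ATF4 list had a median just under 0 and a mean of 0.17. Nor did the RNA interference pathway (2 and 6 of 14, adjusted p = 0.217), the fibroblast and endothelial markers (0 and 0 of 5, adjusted p = 0.852) or the enzymes of inositol phosphates and phosphoinositides, the pathway of IPMK itself (9 and 3 of 33, adjusted p = 0.1). In that pathway the phosphatase INPP4B rose by 1.08 ± 0.13 and the kinase ITPK1 by 0.99 ± 0.14, and the kinases PIP4K2A and ITPKA fell by 1.04 ± 0.11 and 0.86 ± 0.13. Among the passing lists of this comparison given without a second count, the counts adjusted over the list alone were the same. With median scaling fewer falls passed in several of these lists, all still past as lists: 7 falls and 2 rises for homologous recombination, 4 and 2 for the Fanconi list, 6 and 2 for the checkpoint, 9 and 2 for export factors, 15 and 0 for splicing and 12 and 1 for ribosome biogenesis. Ribosomal proteins passed as a list at the preset correlation with that scaling (camera adjusted p = 1.25e-04; 0 rises and 6 falls; adjusted p = 0.619 with an estimated correlation) and without the untreated siIPMK array of experiment 1 (camera adjusted p = 0.0359; adjusted p = 0.491 with an estimated correlation). Leaving out single arrays lowered the falls to as few as 26 for mitosis, 11 for homologous recombination, 4 for the Fanconi list, 8 for the checkpoint, 12 for oxidative phosphorylation and 15 for splicing, and the rises to 7 each for chaperones and interferon response genes. It ended the calls of the chaperone list (camera adjusted p up to 0.161) and the G1/S list (camera adjusted p = 0.0565). With detection required on all 12 arrays the Fanconi and G1/S lists did not pass (camera adjusted p = 0.0568 and 0.112), and the Fanconi median was -0.22 with median scaling.

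Some changes of this comparison were over 1.5 times smaller with other processing. In the authors' values LBH rose by 1.72 and REV3L by 0.55, and MIS18A fell by 1.55, HEYL by 1.54, IDI1 by 1.27, TELO2 by 0.80 and ITPKA by 0.49. With probes averaged SLC25A15 fell by 1.36, and PIP4K2A, at -0.19, did not pass (adjusted p = 0.204). BRCA1 and CCNB1 did not pass with median scaling (adjusted p = 0.0648 and 0.0679), nor MDM2 in the authors' values (adjusted p = 0.0664).

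**Figure D3:**
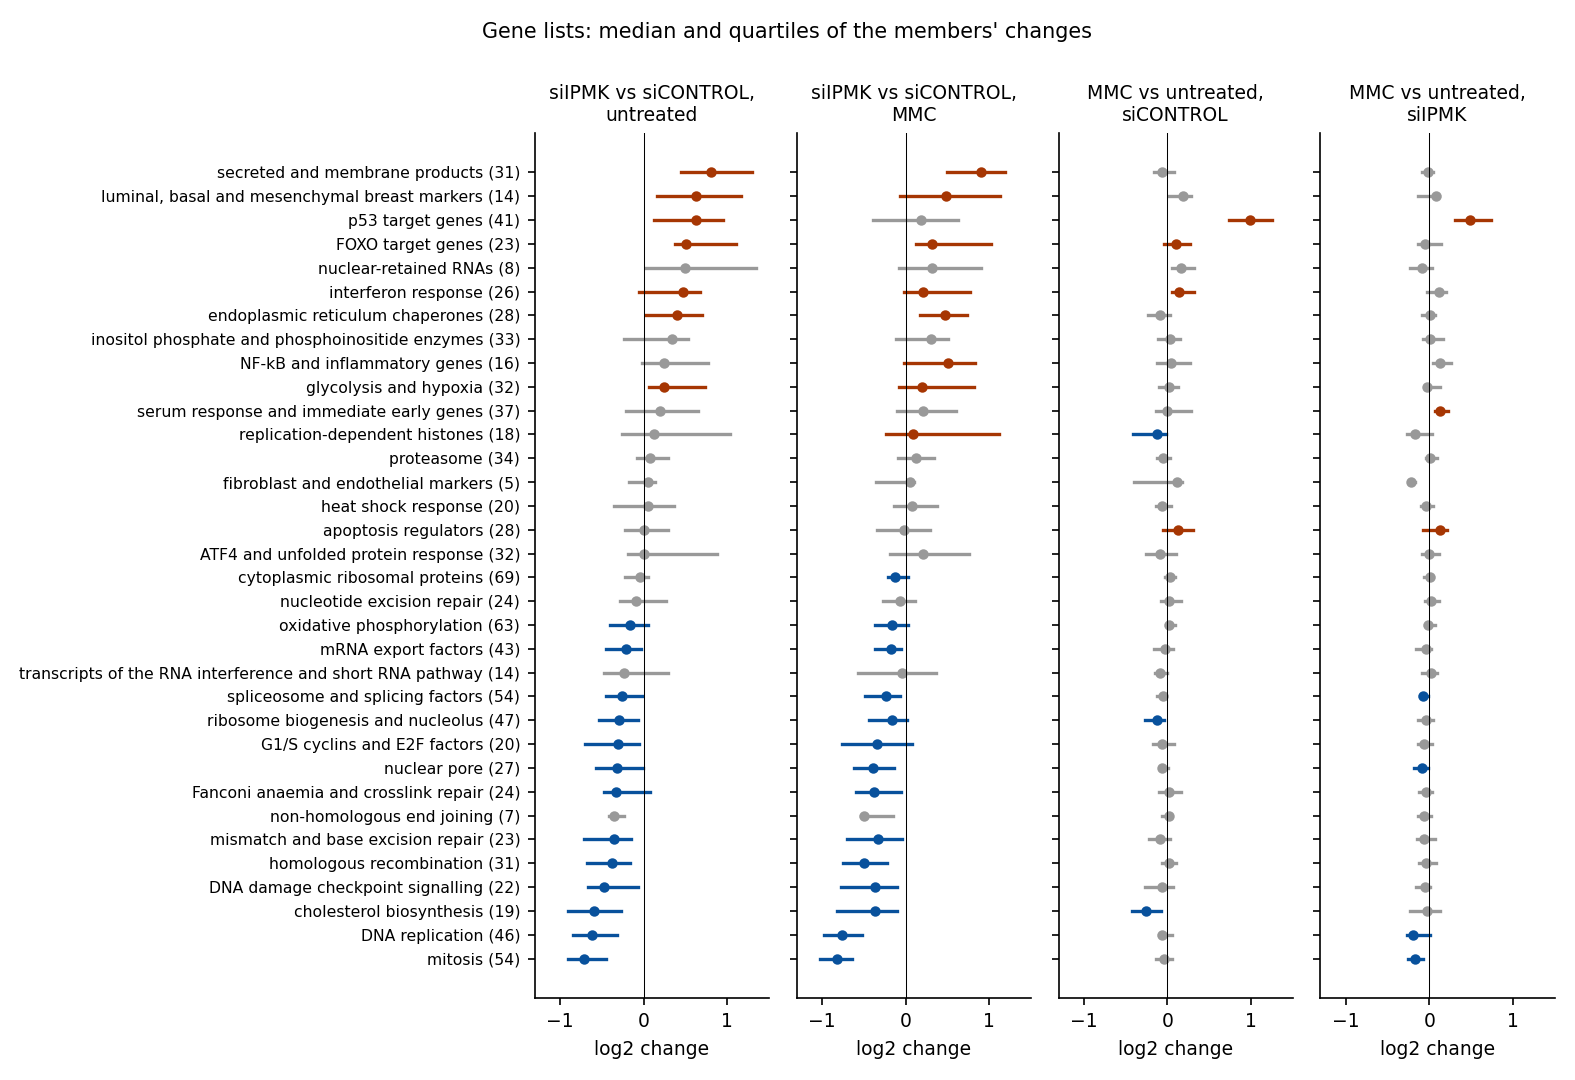
Median (point) and quartiles (line) of the log2 changes of the measured members of each tested list, whose number is in brackets, in 4 comparisons. Orange and blue mark rises and falls with a camera adjusted p under 0.05 at the preset correlation, grey the rest, and the mitosis list lies lowest in both depletion comparisons, at -0.71 and -0.82.

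The second comparison asked the same of cells that had spent 24 hours in MMC. At the preset correlation the lists of mitosis, replication, homologous recombination, crosslink repair and checkpoint genes again passed with medians under 0, and secreted and membrane products with a median over 0. No list passed with an estimated correlation (lowest adjusted p = 0.272). The p53 target list did not pass, and how many of its genes fell depended on the scaling. In limma, 1959 genes rose and 1923 fell, 430 and 301 of them by at least 2-fold. The share of rises was 50.5%, and 69.5% with median scaling, and replicates did not overlap for 49.4% of genes against 10% by chance. DGKB, at least 3.23-fold higher, RPPH1, up by 2.68 ± 0.14 (adjusted p = 8.17e-08), DHRS2, at least 1.97-fold, TDO2, at least 2.24-fold, C1S, at least 2.07-fold, HSPB8, at least 1.94-fold, and CD44, up by 2.29 ± 0.26, were again among the largest rises. SGIP1, an endocytic adaptor, was at least 1.84-fold higher, the cholesterol exporter ABCA1 rose by 2.36 ± 0.25, and HLA-DMA, which loads peptides onto MHC class II, rose by 2.23 ± 0.31 with detection on 2 of 3 control arrays. HEYL (adjusted p = 3.72e-05), TPD52 (adjusted p = 2.32e-04), LRTOMT (adjusted p = 3.03e-05) and TMEM30A (adjusted p = 6.81e-05) passed as falls and were all detected on 1 of 3 siIPMK arrays, so no size is given for them. TK1 fell by 2.75 ± 0.39, SEM1 fell by 2.31 ± 0.31 and the ubiquitin-conjugating enzyme UBE2J1 by 2.16 ± 0.29.

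Under MMC, 0 of 54 mitosis genes rose and 50 fell, 52 adjusted over the list alone, with a median of -0.82 (camera adjusted p = 4.43e-15; adjusted p = 0.3 with an estimated correlation). BIRC5 fell by 2.11 ± 0.28, PLK1 by 1.11 ± 0.22 and CCNB1 by 0.99 ± 0.27. Of 46 replication genes 1 rose and 38 fell, or 2 and 39 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 2.76e-12; adjusted p = 0.272 with an estimated correlation), and CDT1 fell by 1.65 ± 0.14. Homologous recombination had 3 rises and 18 falls among 31, or 3 and 19 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 2.49e-04; adjusted p = 0.272 with an estimated correlation). BRCA1 fell by 0.91 ± 0.17 (adjusted p = 8.84e-04) and its partner BARD1 by 0.78 ± 0.13, and PALB2, at -0.05 ± 0.14, and XRCC2, at -0.37 ± 0.20, did not pass. The Fanconi list had 1 rise and 12 falls among 24 (median -0.38, camera adjusted p = 0.00319; adjusted p = 0.272 with an estimated correlation), with FANCI down by 1.05 ± 0.21 and FANCG by 1.10 ± 0.15. Checkpoint genes had 0 rises and 11 falls among 22, or 1 and 13 adjusted over the list alone (median -0.36, camera adjusted p = 0.00249; adjusted p = 0.272 with an estimated correlation), with CHEK1 down by 0.78 ± 0.14 (adjusted p = 6.64e-04), CDC25C, a phosphatase that starts mitosis, by 1.17 ± 0.22, and ATM at -0.33 ± 0.19 (adjusted p = 0.175). Mismatch and base excision repair had 0 rises and 12 falls among 23 (camera adjusted p = 0.00113; adjusted p = 0.272 with an estimated correlation). Nucleotide excision repair (adjusted p = 0.395) and end joining (adjusted p = 0.053) did not pass, though end joining did with median scaling (camera adjusted p = 0.0458; adjusted p = 0.565 with an estimated correlation).

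Export factors had 1 rise and 13 falls among 43, or 1 and 10 adjusted over the list alone (median -0.17, camera adjusted p = 0.00218; adjusted p = 0.3 with an estimated correlation), and ALYREF fell by 0.50 ± 0.19 (adjusted p = 0.0497), with overlap between the replicates. Secreted and membrane products had 22 rises and 2 falls among 31, or 24 and 2 adjusted over the list alone (median 0.90, camera adjusted p = 5.17e-06; adjusted p = 0.366 with an estimated correlation), though B2M, the light chain of MHC class I, fell by 1.46 ± 0.25. Chaperone and translocon genes had 13 rises and 2 falls among 28, or 15 and 2 adjusted over the list alone (median 0.47, camera adjusted p = 0.00319; adjusted p = 0.482 with an estimated correlation), with DNAJB9 up by 1.73 ± 0.30 and the chaperones HSPA5 and MANF down by 0.88 ± 0.16 and 1.15 ± 0.19. Inflammatory NF-kB genes had 8 rises and 0 falls among 16 (median 0.51, camera adjusted p = 0.0397; adjusted p = 0.272 with an estimated correlation), led by interleukin 1 alpha, IL1A, not detected on control arrays and at least 2.04-fold higher. FOXO targets had 10 rises and 0 falls among 23 (camera adjusted p = 0.00218; adjusted p = 0.272 with an estimated correlation), and cholesterol genes had 1 rise and 10 falls among 19 (camera adjusted p = 0.00249; adjusted p = 0.272 with an estimated correlation). Of 18 replication-dependent histones 8 rose and 2 fell (camera adjusted p = 0.0479; adjusted p = 0.3 with an estimated correlation), with H2AC6 up by 1.70 ± 0.15, H2BC12 by 1.67 ± 0.14 and H2BC5 by 1.64 ± 0.13. Of 41 p53 targets 12 rose and 11 fell, or 13 and 11 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.268). With median scaling 16 rose and 4 fell, and without the siIPMK MMC array of experiment 2, 11 rose and 5 fell. In this list GDF15 rose by 1.74 ± 0.27, GADD45A by 0.92 ± 0.14 and CDKN1A by 0.89 ± 0.15, and MDM2 was at 0.17 ± 0.27 (adjusted p = 0.63). The probe used for BAX, a pro-apoptotic BCL2 relative, fell by 0.76 ± 0.14, while the dimmer probe of the same gene rose by 0.86 (adjusted p = 3.04e-04), so BAX has no settled direction here.

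Further lists passed under MMC at the preset correlation. Nuclear pore genes had 3 rises and 12 falls among 27, or 3 and 14 adjusted over the list alone (camera adjusted p = 0.00249; adjusted p = 0.272 with an estimated correlation). Splicing factors had 0 and 21 among 54 (camera adjusted p = 3.93e-05; adjusted p = 0.3 with an estimated correlation) and ribosome biogenesis 1 and 17 among 47 (camera adjusted p = 0.00836; adjusted p = 0.414 with an estimated correlation). Oxidative phosphorylation had 3 and 21 among 63, or 3 and 20 adjusted over the list alone (camera adjusted p = 0.00301; adjusted p = 0.272 with an estimated correlation). The G1/S list had 3 and 10 among 20, or 3 and 11 adjusted over the list alone (camera adjusted p = 0.0397; adjusted p = 0.272 with an estimated correlation). Ribosomal proteins had 1 rise and 13 falls among 69, or 0 and 10 adjusted over the list alone (camera adjusted p = 0.0397; adjusted p = 0.535 with an estimated correlation). Glycolysis and hypoxia genes had 13 rises and 2 falls among 32, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.394 with an estimated correlation). Interferon response genes had 10 rises and 2 falls among 26 (camera adjusted p = 0.048; adjusted p = 0.366 with an estimated correlation), and breast lineage markers 7 and 0 among 14 (camera adjusted p = 0.0175; adjusted p = 0.272 with an estimated correlation). Nuclear-retained RNAs, with 4 rises and 2 falls among 8, did not pass (camera adjusted p = 0.318), and neither did the enzymes of inositol phosphates (9 and 3 of 33, camera adjusted p = 0.12). With median scaling the falls and rises were 7 and 1 for the Fanconi list, 8 and 1 for the checkpoint, 7 and 1 for export factors, 12 and 1 for oxidative phosphorylation, 13 and 0 for splicing and 4 and 2 for ribosome biogenesis, and these lists still passed. Leaving out single arrays lowered the falls to as few as 7 for the Fanconi list, 8 for export factors, 12 for oxidative phosphorylation, 13 for splicing, 9 for ribosome biogenesis and 8 for ribosomal proteins, and the rises to 7 for chaperones and 5 each for interferon response and NF-kB genes. It ended the calls of histones (camera adjusted p up to 0.146), ribosomal proteins (up to 0.103), the interferon response (up to 0.0832), NF-kB genes (up to 0.0683) and the G1/S list (0.0512). With detection required on all 12 arrays the lists of NF-kB genes (camera adjusted p = 0.172), ribosomal proteins (0.0778), the G1/S list (0.0776), histones (0.0675) and the interferon response (0.0658) did not pass, nor did the last 2 in the authors' values (0.0508 for both). The NF-kB median was 0.25 in the authors' values, and with median scaling the medians were -0.24 for the Fanconi list, -0.20 for the checkpoint and -0.09 for export factors. In the authors' values HLA-DMA rose by 1.38 and H2AC6 by 1.07 and HSPA5 fell by 0.43, each over 1.5 times less. ALYREF did not pass with median scaling (adjusted p = 0.135).

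The depletion effects without and with MMC, which share no arrays but come from the same experiments where the numbers pair the arrays, had a Pearson r of 0.916 and a Spearman rho of 0.896 across 9409 genes, which are not independent replicates. Signs matched for 86.02% of genes. Of the rises 1469 were shared, where independent lists would share 400.2, and of the falls 1457, where they would share 382. Where experiments are shared the 2 effects are not independent, so the overlaps by chance are only a guide. Opposite calls were made for 4 genes. Averaged over both treatments, 2770 genes rose and 2683 fell, with all 12 arrays taken as independent, and with the arrays of each pair averaged first 2118 rose and 2126 fell. Rises were 50.8% of the calls over all 12 arrays, and 67.4% with median scaling. In the mean effect over all 12 arrays RPPH1 was at 2.89 ± 0.10 and CD44 at 2.42 ± 0.18, and ALYREF fell by 0.47 ± 0.14 (adjusted p = 0.00857).

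**Figure D4:**
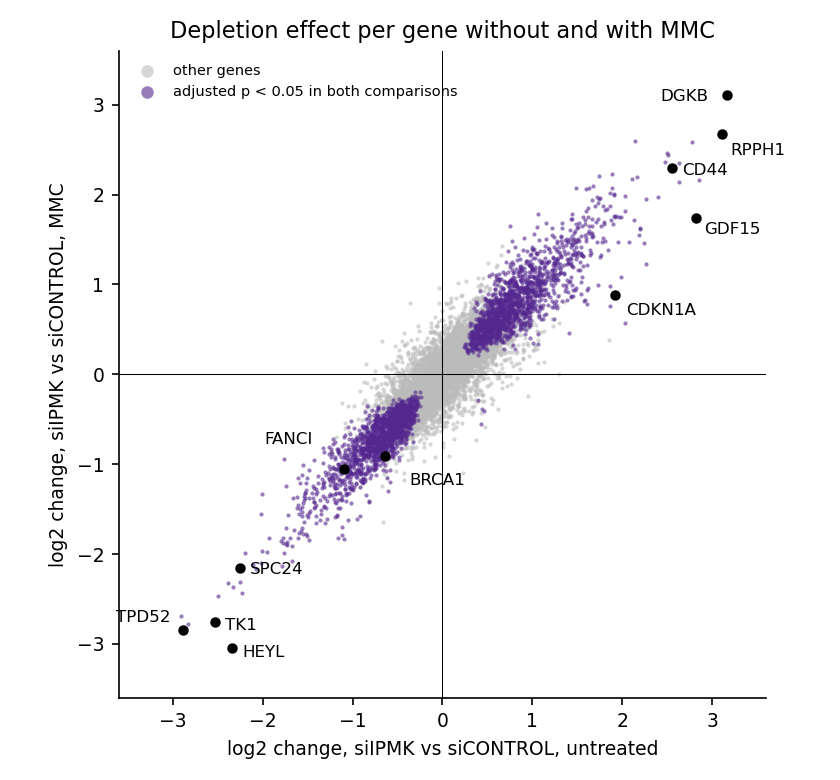
Log2 change after IPMK depletion without MMC (x axis) and with MMC (y axis) for 9409 genes, with genes past an adjusted p of 0.05 in both comparisons in purple and 11 genes named. The points lie along the diagonal, with r = 0.916 across genes.

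The third comparison asked what MMC did to cytoplasmic transcripts in cells with control siRNA. MMC raised p53 target genes, which made up 29 of the 184 rises, and many more genes passed once the arrays were paired. GDF15 rose by 2.63 ± 0.27 (log2, n = 3, adjusted p = 4.47e-05), CDKN1A by 1.97 ± 0.15 (adjusted p = 4.23e-06) and PHLDA3, an inhibitor of AKT, by 1.86 ± 0.14 (adjusted p = 4.23e-06). In limma, 184 genes rose and 10 fell, and with the terms for pairs of arrays 581 rose and 369 fell. Replicates did not overlap for 21.4% of genes, where chance gives 10%. INKA2, an inhibitor of PAK4, rose (adjusted p = 6.36e-07), with detection on 1 of 3 untreated arrays and no size given, and DPYSL4, a p53-responsive metabolic gene, rose by 1.94 ± 0.17. Undetected without MMC and higher with it were UBASH3B, a phosphatase, at least 3.12-fold, MYBPHL at least 2.96-fold, DENND2D at least 2.51-fold, ALG1L1P at least 1.68-fold and CFAP144 at least 1.56-fold. MDM2 was not detected on untreated arrays, was detected on 2 of 3 MMC arrays, and was at least 1.05-fold higher (adjusted p = 0.022).

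Of the 10 falls, 6 were by at least 1.5-fold in the fit and 1 by at least 2-fold, dim probes included. MIX23, a mitochondrial protein gene, fell by 0.92 ± 0.18 (adjusted p = 0.0116), the sterol regulator INSIG1 by 0.76 ± 0.18 and the squalene epoxidase SQLE by 0.70 ± 0.17. ASNS, the asparagine synthetase, fell by 0.67 ± 0.14, the arginine carrier SLC7A1 by 0.60 ± 0.13, the Wnt receptor FZD2 by 0.56 ± 0.14, NDUFAF4 by 0.47 ± 0.11, ARHGDIA by 0.43 ± 0.10 and the replicative helicase subunit MCM6 by 0.41 ± 0.10. WDR24, of a nutrient-sensing complex, was detected on 1 of 3 untreated arrays and 0 of 3 MMC arrays, and was at least 1.01-fold lower. Without the untreated control array of experiment 2, 115 genes rose and 0 fell, and without the MMC control array of experiment 2, 119 rose and 2 fell.

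Of 41 p53 targets 29 rose with MMC and 0 fell, 36 and 0 adjusted over the list alone, with a median of 0.99 (camera adjusted p = 4.40e-62; adjusted p = 5.18e-04 with an estimated correlation). With terms for the pairs the estimated correlation gave adjusted p = 0.0889. PMAIP1, the BH3-only gene NOXA, rose by 1.82 ± 0.14, with detection on 2 of 3 untreated arrays, and SESN1, a sestrin, by 1.55 ± 0.13. XPC, the damage sensor of nucleotide excision repair, rose by 1.13 ± 0.13, and DDB2, its partner, was at least 1.45-fold higher (adjusted p = 0.0488). None of the 54 mitosis genes passed in limma (0 at adjusted p under 0.05), the list's median was -0.04 (camera adjusted p = 0.554), and among 46 replication genes TYMS rose by 0.56 ± 0.13 and MCM6 fell. With terms for the pairs 3 mitosis genes rose and 2 fell, and 3 replication genes rose and 3 fell. For homologous recombination, the Fanconi list and checkpoint genes the counts in limma were 0 rises and 0 falls, with camera adjusted p values of 0.554, 0.576 and 0.248. With the pairs 1 gene rose in each of these 3 lists, REV3L among them (0.56 ± 0.13, adjusted p = 0.00474 in that fit), and 1 checkpoint gene fell. CHEK1 was at -0.16 ± 0.14, FANCI at 0.10 ± 0.21 and BRCA1 at 0.10 ± 0.17, with adjusted p values of 0.746, 0.933 and 0.914.

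At the preset correlation 6 further lists passed, also with the pairs. Apoptosis regulators had 2 rises among 28, PMAIP1 and BAX, both p53 targets as well (camera adjusted p = 0.00492; adjusted p = 0.0797 with an estimated correlation). Cholesterol genes had 2 falls among 19, INSIG1 and SQLE, with a median of -0.25 (camera adjusted p = 0.00363; adjusted p = 0.343 with an estimated correlation). Ribosome biogenesis had a median of -0.13 with 0 of 47 genes past in limma (camera adjusted p = 6.45e-06; adjusted p = 0.379 with an estimated correlation). Interferon response genes had a median of 0.14 and 1 rise, of TRIM22, a p53 target as well, by 1.12 ± 0.17 (camera adjusted p = 0.0108; adjusted p = 0.379 with an estimated correlation). Neither the apoptosis nor the interferon list was tested without its p53 targets. FOXO targets had 2 rises, of SESN1 and GADD45A, both p53 targets as well (camera adjusted p = 0.0481; adjusted p = 0.4 with an estimated correlation), and without these 2 genes the list did not pass (camera adjusted p = 0.457; adjusted p = 0.856 with an estimated correlation). Histones had a median of -0.12 with 0 genes past in limma (camera adjusted p = 0.0191; adjusted p = 0.379 with an estimated correlation, and camera adjusted p = 0.052 with median scaling). With terms for the pairs the rises and falls were 5 and 0 for apoptosis regulators, 1 and 5 for cholesterol, 0 and 8 for ribosome biogenesis, 7 and 1 for the interferon response, 6 and 0 for FOXO targets and 0 and 4 for histones. Leaving out single arrays ended the calls of FOXO targets (camera adjusted p up to 0.298), the interferon response (up to 0.157) and histones (up to 0.143). In the authors' values the interferon median was 0.07 and that of histones -0.08, and FOXO targets did not pass (camera adjusted p = 0.0541). There TRIM22 rose by 0.59 and PMAIP1 by 1.01, each over 1.5 times less, and MDM2 did not pass (adjusted p = 0.0838). NDUFAF4 did not pass with probes averaged (adjusted p = 0.349), nor TYMS, MCM6 and DDB2 with median scaling (adjusted p = 0.244, 0.0884 and 0.0789). The median of ribosome biogenesis was -0.21 with that scaling.

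The fourth comparison asked the same of MMC in IPMK-depleted cells. Again p53 targets rose, and they made up 13 of the 33 rises. GDF15 rose by 1.56 ± 0.27 (n = 3, adjusted p = 0.019), CDKN1A by 0.93 ± 0.15 (adjusted p = 0.0141) and RGS16, a regulator of G-protein signalling, by 1.47 ± 0.19 (adjusted p = 0.00355). Undetected without MMC were the guanylate cyclase ligand GUCA2B, at least 2.37-fold higher, the pseudogene CELP, at least 2.00-fold, and the homeobox gene NKX2-5, at least 1.66-fold. MIX23 fell by 1.14 ± 0.18 (adjusted p = 0.0129) and was the only fall. In limma, 33 genes rose and 1 fell, and all 33 rises were among the 184 of control siRNA, where independent lists would share 0.645. Replicates did not overlap for 9.85% of genes, no more than the 10% that chance gives. With terms for the pairs 184 rose and 94 fell. With median scaling 12 rose and 1 fell, and leaving out single arrays gave 13 to 31 calls, the fewest without the untreated siIPMK array of experiment 2.

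Of 41 p53 targets 13 rose and 0 fell, 22 and 0 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 1.43e-40; adjusted p = 0.00248 with an estimated correlation, and 0.119 with terms for the pairs). The count of rises was 22 with terms for the pairs, 4 with median scaling and between 5 and 10 without single arrays. TP53I3, a quinone reductase gene of the p53 response, rose by 1.17 ± 0.13, PMAIP1 by 1.08 ± 0.14, PHLDA3 by 0.87 ± 0.14 and ZMAT3 by 0.83 ± 0.13. MDM2 was at 0.53 ± 0.27 (adjusted p = 0.926). Mitosis and replication lists had medians of -0.17 and -0.19 with 0 genes past in limma (camera adjusted p = 8.54e-06 and 9.72e-06; adjusted p = 0.725 with an estimated correlation for both). With terms for the pairs 7 mitosis and 6 replication genes fell and 0 rose, MCM6 among them (-0.44 ± 0.08, adjusted p = 0.00231 in that fit). Both list calls hung on single arrays. Without the untreated siIPMK array of experiment 1 the medians were 0.03 for mitosis and -0.01 for replication (camera adjusted p = 0.975 and 0.677), and without the siIPMK MMC array of experiment 2 they were 0.002 and -0.06 (camera adjusted p = 0.645 and 0.139). Serum response genes had a median of 0.12 and apoptosis regulators of 0.13 (camera adjusted p = 0.00114 and 0.0399; adjusted p = 0.301 and 0.3 with an estimated correlation). The apoptosis list was not tested without the p53 targets it holds. Nuclear pore genes and splicing factors had medians of -0.09 and -0.07 (camera adjusted p = 0.021 for both; adjusted p = 0.725 with an estimated correlation for both). Leaving out single arrays ended the calls of splicing factors (camera adjusted p up to 0.975), nuclear pore genes (up to 0.524) and apoptosis regulators (up to 0.217). With the pairs serum response genes had 3 rises and apoptosis regulators 2, and histones (camera adjusted p = 0.0448), export factors (0.0473), interferon response (0.0473) and NF-kB genes (0.0473) passed as lists as well, and with an estimated correlation these 4 had adjusted p from 0.215 to 0.304. CHEK1, FANCI, BRCA1 and ALYREF were at -0.31 ± 0.14, 0.15 ± 0.21, -0.17 ± 0.17 and 0.04 ± 0.19, and none of these 4 passed, with the lowest adjusted p of them, 0.825, at CHEK1. The calls that ended without some single array were those of GDF15 (adjusted p up to 0.1), CDKN1A (up to 0.0698), PHLDA3 (0.0685), MIX23 (up to 0.0631) and ZMAT3 (up to 0.0612). Median scaling ended those of PHLDA3 (0.1) and ZMAT3 (0.0639). In the authors' values RGS16 and PMAIP1 both rose by 0.72, over 1.5 times less, and ZMAT3 did not pass with probes averaged (adjusted p = 0.4). The serum response median was 0.07 with median scaling, and apoptosis regulators did not pass with detection required on all 12 arrays (camera adjusted p = 0.233).

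The last comparison asked whether MMC acted differently after depletion. The p53 target list differed, and whether single genes passed depended on the fit. The difference between the MMC changes, siIPMK minus control siRNA, had a median of -0.53 over the 41 p53 targets, and it was below 0 for 39 of them (camera adjusted p = 1.31e-27; adjusted p = 0.00958 with an estimated correlation). In the authors' values the median was -0.30. With an estimated correlation that call was lost with terms for the pairs (adjusted p = 0.227) and with median scaling (adjusted p = 0.086). Their median level was 8.73 with control siRNA, 10.28 with control siRNA and MMC, 9.48 with siIPMK and 10.33 with siIPMK and MMC, so the medians with MMC lay close together and those without it apart. Under MMC some members were higher and others lower after depletion, so the close medians do not show that single genes reached the same level. CDKN1A differed by -1.04 ± 0.22 (adjusted p = 0.275; -0.43 with probes averaged), PHLDA3 by -0.98 ± 0.20 (adjusted p = 0.275), SESN1 by -0.81 ± 0.18 (adjusted p = 0.336) and RPS27L, a ribosomal protein paralog, by -0.64 ± 0.11 (adjusted p = 0.121). Over all genes limma called 0 and 327 had an unadjusted p under 0.05, while array weights gave 34 genes and leaving out both siIPMK arrays of experiment 1 gave 15. The lowest adjusted p was 0.0832, at INKA2, detected on 1 of 3 untreated control arrays, and at MYBPHL and S100Z, which no untreated control array detected, so that no size is given for them. PDLIM1 was at -0.68 ± 0.13 (adjusted p = 0.152). The lowest p values for a positive difference were those of CYRIB (0.71 ± 0.17, or 0.29 with probes averaged), TAGLN, a smooth muscle actin-binding protein gene (0.50 ± 0.13), ETV4 (0.65 ± 0.20), and TBC1D17 and LMO2, each undetected in 1 group, with adjusted p from 0.589 to 0.999. With terms for the pairs 60 genes passed, 11 higher and 49 lower, and 13 of the 49 were p53 list genes. In that fit CDKN1A (adjusted p = 7.93e-05), GDF15 (-1.08 ± 0.16, adjusted p = 4.85e-04), PHLDA3 and INKA2 were lower and TAGLN was higher.

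**Figure D5:**
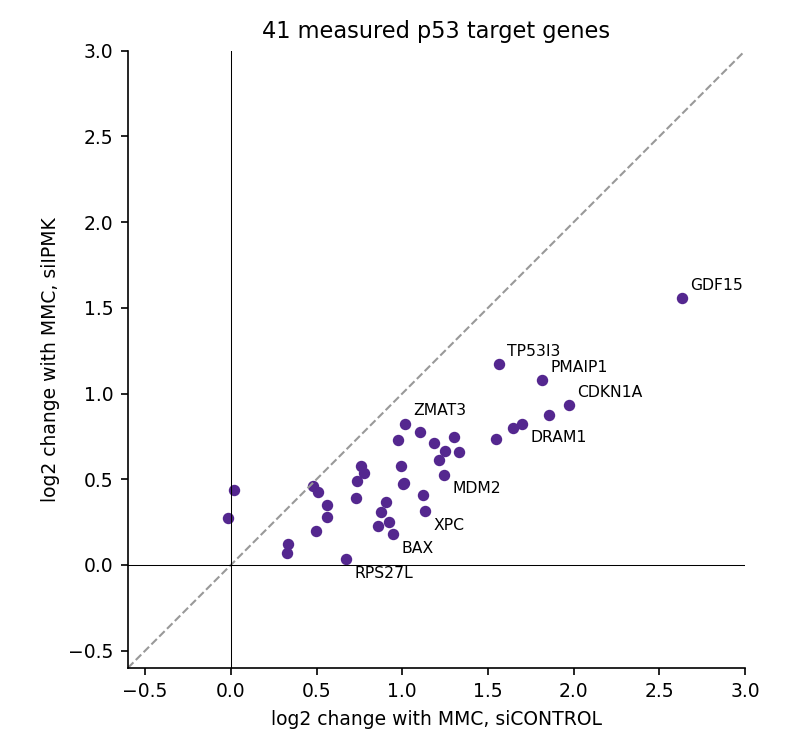
Log2 change with MMC of the 41 measured p53 target genes under control siRNA (x axis) and siIPMK (y axis), with the line of equal change dashed. Of the 41 points 39 lie below the line.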

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

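The tests of a shared batch, swapped labels, membrane-bound RNA, nuclear leak and admixture by array and scaling, the splits that keep the pairs, the restriction to splits that part them, the FOXO list without p53 targets, and the fit with pairs, were chosen after the results were seen, and those of bright probes, experiment 1 alone and the other splits before. The bound for admixture set before, an interval more than 0.05 from 0 in both treatments, was met by the quantile normalized values, but it took no account of the scaling, so it was not used to judge admixture, and tests by array and scaling were added. Intervals of this section, in brackets where printed, are 95% intervals from 10000 resamplings of genes. Genes are not independent replicates, so these intervals do not measure the spread between arrays.

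The siIPMK arrays of experiment 1 lay between the controls and the siIPMK arrays of experiments 2 and 3, at 0.565 without MMC and 0.553 with it on an axis from 0 for controls to 1 for those experiments. A batch that shifted all arrays of that experiment alike is argued against. The deviations of these siIPMK arrays had correlations across genes of only 0.0876 and 0.0553 with the control arrays of the same number, and genes are not independent replicates. A smaller shared batch cannot be told apart from other causes. Experiment 1 had the lowest array weight in each group, at 0.705 and 0.658 for controls and 0.298 and 0.216 for siIPMK. Its control arrays also lay nearest to siIPMK on the axis, at 0.0901 and 0.0984. Swapped labels are argued against, since the highest control array lay at 0.0984. One share of control RNA in the array without MMC is argued against, since the share implied by risen genes exceeded that of fallen genes by 0.176, by 0.144 with median scaling and by 0.187 with cyclic loess. In the MMC array it cannot be told apart from other causes, since the difference of 0.204 turned to -0.116 with median scaling. Weaker depletion in that experiment may also give such a position, and it stays open because IPMK was not measured.

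The p53 targets rose less with MMC after depletion, with a median difference of -0.533, or -0.299 in the authors' values. Saturation of bright probes is argued against as the whole cause, since the 20 dimmer members still had a median difference of -0.291 (from -0.694 to -0.226) beside -0.556 for the 21 brighter ones. That interval covers only the spread between genes. The siIPMK arrays of experiment 1 alone are argued against, since without them the median was -0.632. The list's call with an estimated correlation depended on the fit, with adjusted p = 0.227 with terms for the pairs and 0.086 with median scaling. A higher level before MMC might leave less room for a rise, and whether that or a changed response to damage is at work stays open.

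Secreted and membrane products rose with depletion, with a median of 0.83 (from 0.544 to 1.10) for the mean effect, and did not pass with an estimated correlation (adjusted p = 0.326). More membrane-bound RNA in the fraction cannot be told apart from other causes. Chaperone and translocon transcripts had a smaller median of 0.463, and the difference was 0.367 (from 0.029 to 0.767), with quantile normalization only. Members of that list moved both ways, with HSPA5 and MANF down and DNAJB9 up under MMC. Their own regulation may therefore shift its median whatever the fraction holds. A leak of nuclear RNA cannot be told apart from other causes, with a median of 0.398 (from -0.509 to 1.27) over 8 nuclear-retained RNAs that went both ways, among them RPPH1 at 2.89, TUG1 at -0.51 and SCARNA9, which fell with detection on 2 and 1 of 3 siIPMK arrays without and with MMC.

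Splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real grouping alone reached its own count, 1 of 10, for depletion without MMC (3790, highest other 0), depletion with MMC (3882, highest other 0) and MMC with control siRNA (194, highest other 0). For MMC with siIPMK 2 of 10 did, since 1 other split gave 219 genes against the real 34. That split keeps both arrays of experiment 1 together, but other splits that do so gave 0 genes, so this does not account for its count. Among the 4 splits that part all pairs, a restriction not set before, the real one had 34 and the others 0. For the mean depletion effect the splits that keep the pairs whole also number 10, too few for a share under 0.05, and the real one alone, 1 of 10, reached 5453 (highest other 0), or 4244 with the pairs averaged (highest other 0). The 100 splits first planned and drawn, of which 1 reached 5453 with 2786 the highest other, broke the pairs, so they are not used to judge chance. For the difference between the MMC changes the real count was 0, so 100 of 100 permutations reached it, with 584 the highest.

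Further lists differed between the MMC changes at the preset correlation. The median difference was -0.126 for DNA replication (camera adjusted p = 0.0147; adjusted p = 0.855 with an estimated correlation) and -0.149 for mitosis (camera adjusted p = 0.0111; adjusted p = 0.855 with an estimated correlation). These 2 medians depended on single arrays, at 0.014 and 0.02 without the untreated siIPMK array of experiment 1, -0.005 and 0.013 without the siIPMK MMC array of experiment 2, and -0.271 and -0.37 without that of experiment 1. It was -0.183 for nuclear-retained RNAs (camera adjusted p = 0.0129; adjusted p = 0.19 with an estimated correlation) and -0.123 for FOXO targets (camera adjusted p = 0.0446; adjusted p = 0.518 with an estimated correlation). It was 0.133 for cholesterol biosynthesis (camera adjusted p = 0.0251; adjusted p = 0.484 with an estimated correlation) and 0.065 for ribosome biogenesis (camera adjusted p = 0.00174; adjusted p = 0.697 with an estimated correlation). Leaving out single arrays ended each of these 4 calls too, with camera adjusted p up to 0.0765 for nuclear-retained RNAs, 0.356 for FOXO targets, 0.192 for cholesterol and 0.0752 for ribosome biogenesis. The FOXO list holds p53 targets, and in this comparison it was not tested without them. In the authors' values FOXO targets did not pass (camera adjusted p = 0.0588) and the nuclear-retained median was -0.104, and with median scaling that of replication was -0.079. Of 1742 unnamed probes 925 passed for the mean depletion effect with all arrays taken as independent, 411 up and 514 down.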

How the results depend on the processing

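Across the alternatives 25214 of 25741 gene values and 5386 of 5604 list values kept their call, and 1 gene value reversed, that of BAX for depletion with MMC, at 0.045 (adjusted p = 0.763) with its probes averaged, because its probes move in opposite directions. Most of these genes were named for large changes or low adjusted p in the main fit, so many calls were likely to hold by selection. A gene called in neither fit counted as kept even where its sign turned. Array weights, the random block and the variance models do not enter the list test. Their 204 list values each kept their call by construction, are part of the 5604 and say nothing of robustness. For depletion without MMC the count was 2254 with a change of at least 1.5-fold and 2239 at an adjusted p under 0.01, for depletion with MMC 2300 and 2421, and for the mean effect 2286 with at least 1.5-fold. For MMC with control siRNA it was 534 with array weights, 116 at an adjusted p under 0.01 and 448 without both siIPMK arrays of experiment 1. For MMC with siIPMK it was 13 with median scaling, 21 with detection on all 12 arrays, 103 with array weights, 9 at an adjusted p under 0.01, 18 without those arrays of experiment 1 and 6 with only the 2 groups compared. For the difference between MMC changes it was 1 with the authors' values, 1 with each probe on its own, 34 with array weights and 15 without those arrays. The correlation of depletion effects across genes, which are not independent replicates, was 0.927 with no background correction, 0.930 with the authors' values, 0.907 with no detection filter and 0.925 with detection on all 12 arrays. That of MMC effects was 0.414 with array weights and 0.405 without the siIPMK arrays of experiment 1, and the cause of these shifts was not tested. Signal over background limits the folds of dim probes. Only folds of probes undetected on a whole group are given as lower bounds.

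With a block for the experiment number the counts were 4424 and 4419 for depletion without and with MMC, 281 and 39 for MMC with control siRNA and siIPMK, 0 for the difference and 5853 for the mean effect, and a random block gave 3 for the difference. The depletion arrays share only a number, and their correlations of deviations were 0.0876, 0.123 and 0.125 without MMC and 0.0553, 0.195 and -0.022 with it. Of the 6 arrays 6 correlated best with their own number without MMC and 3 with it, a hint from the data and not the design. An alternative by slide was not run, since the slide of each array is not recorded. Pairing within each siRNA, chosen after the data were seen, gave 950 and 278 for the MMC comparisons and 60 for the difference, and averaging the arrays of each pair, also chosen then, gave 4244 for the mean depletion effect.

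Leaving out single arrays gave 2537 to 4393 genes for depletion without MMC, 2751 to 4565 with MMC, 4873 to 5879 for the mean effect, 115 to 267 for MMC with control siRNA, 13 to 31 with siIPMK and 0 to 7 for the difference, with correlations of 0.892 to 0.925 and 0.362 to 0.513. For MMC with control siRNA it was 115 without the untreated and 121 without the MMC control array of experiment 2. For MMC with siIPMK it was 22 without that MMC control array, 15, 13 and 16 without the untreated siIPMK arrays of experiments 1 to 3, and 19 and 17 without the siIPMK MMC arrays of experiments 2 and 3. The difference had 1 gene without the untreated control array of experiment 1, and 3 and 7 without the untreated and the MMC siIPMK array of experiment 1.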

Other observations

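Some gene families outside the lists were looked at because of their values, and no test of enrichment was made. In the mean depletion effect 58.0% of all genes passed. That fit took all arrays as independent, although untreated and MMC arrays of the same number were taken as pairs within each siRNA. With the arrays of each pair averaged first, the count of genes was 4244 in place of 5453. Errors, adjusted p values and calls of this section are from the fit without pairs and may overstate the precision. The families were not tested with the pairs averaged. In the mean depletion effect all 7 measured metallothioneins, which bind zinc and copper, fell, with a median of -1.03. MT1M fell most, by 1.87 ± 0.18 (adjusted p = 2.34e-06), and MT2A fell by 0.75 ± 0.11. All 7 also fell with median scaling, cyclic loess and the authors' values. These genes are close paralogs, and sharing of signal between their probes was not examined. Of 8 HES and HEY repressors, many of them Notch targets, 5 fell, 1 rose and 2 did not pass under each of these scalings, among them HES2, undetected without MMC. HEYL (adjusted p = 8.30e-07) and HES5 (adjusted p = 0.00325) fell, with detection on 1 of 3 siIPMK MMC arrays, so no size is given. HEY1 was at -1.87 ± 0.19 and HEY2 at -0.88 ± 0.09, HES6 rose by 0.41 ± 0.08, and HES1 was at -0.10 ± 0.43 (adjusted p = 0.854). The receptor NOTCH3 fell by 0.81 ± 0.12 (adjusted p = 5.12e-05), while NOTCH1, at 0.29 ± 0.16 (adjusted p = 0.144), did not pass.

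Of 16 measured subunits of the V-ATPase, the proton pump of lysosomes, 10 rose and 4 fell in the mean depletion effect, and 2 fell with median scaling. These genes too were chosen after their values were seen. ATP6V1A rose by 1.29 ± 0.11 (adjusted p = 9.54e-07) and ATP6V0E1 by 0.88 ± 0.11, while ATP6V1C1 fell by 0.73 ± 0.14 (0.46 in the authors' values). Both chains of HLA-DM rose, HLA-DMA by 2.06 ± 0.22 (1.27 in the authors' values), with detection on 2 of 3 arrays of each control group, and HLA-DMB by 1.78 ± 0.23, and so did the secretoglobins SCGB2A1 by 1.92 ± 0.15 (1.62 in the authors' values) and SCGB1D2 (adjusted p = 8.43e-07), the latter detected on 1 of 3 untreated control arrays and given no size. The siRNA sequences were not used here, so silencing of other transcripts was not examined.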
